A study of Mus musculus with 39 samples.

How the data were processed

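RNA from sorted mouse brain macrophages was sequenced at 6 embryonic stages in 2 populations, microglia and border-associated macrophages (BAM), giving 39 libraries in 12 groups. Reads were aligned with STAR to GRCm38 and assigned to genes with featureCounts, per the submitters' processing notes, and the deposited table holds counts per gene and library. Versions of these programs and the annotation release were not given in the sources used here. ERCC spike-ins were added per the protocol and were not used here. The counts are not based on molecular tags, so intervals and lower bounds from counts cover no more than counting error. Counts of 2 were more frequent than counts of 1 (49977 against 21280 cells), and 4 more than 3 (30062 against 12637). Counts of 6 were also more frequent than counts of 5 (21412 against 9621). This excess of even counts goes with both reads of a pair being counted, although the sources do not say so. With 2 counts then for 1 fragment, the counting intervals are to be read as too narrow and the lower bounds as too high. Library totals ran from 10.7 to 47.2 M counts with a median of 22.4 M.

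Of 53379 gene identifiers, 53274 carried a symbol and 105 did not. Genes were filtered with filterByExpr, which left 22061 holding 99.973% of the counts. Normalization factors were TMM, and a quasi-likelihood model with 1 coefficient per group was fitted in edgeR 4.0.16 under R 4.3.3 (27 residual degrees of freedom, common biological coefficient of variation 55.08%). Adjusted p-values are Benjamini-Hochberg values from edgeR over the tested genes, with calls at 0.05, and errors after ± are standard errors of log2 fold changes from the same fit or, for levels in CPM (counts scaled to the library total), standard deviations over libraries. The 12 comparisons were BAM against microglia at each stage and as the mean over the 6 stages, E18.5 against E10.5 and against E12.5 in each population, and the population-by-stage contrast of the 2 E18.5 to E10.5 changes. A positive log2 value means higher in BAM or higher at E18.5.

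Gene lists were fixed before the counts were seen: microglia core, BAM core, MHC class II, mitosis, DNA replication, haematopoietic progenitor, interferon response, immediate early and heat shock, lysosome, complement, cytokines and chemokines, iron and haem handling, scavenger and endocytic receptors, TGF-beta signalling, macrophage transcription factors, glycolysis, cholesterol synthesis, and markers of monocytes, granulocytes and mast cells, erythroid, endothelial, neural, mesenchymal and mural, and lymphoid cells. Each was counted over all tested genes and again adjusted over the list alone, and lists of at least 5 genes were tested with camera from limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation. The glycolysis list of 17 symbols matched 18 tested identifiers because Aldoa has 2. Genes named in the text followed a rule fixed beforehand: the 10 largest changes each way (5 for single stages and for E12.5) among called genes with average log2 CPM of at least 4, up to 4 members of each list by p, and a panel of known markers, leaving out predicted and clone names and a few genes not reported here.

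Where all libraries of a group had 0 counts the fold is a lower bound that places 3 counts in that group, and where a group held 1 to 3 counts the ratio has its 95% counting interval. Principal components used the 500 most variable genes with a prior count of 2. Simulated counts with known changes tested the fit: 5 false calls arose at E10.5, 2 at E14.5 and 17 for the mean over stages, and a list with an added shift was called in 1 of 1 case against 0 of 20 random lists. The simulated genes varied independently of each other. The 0 of 20 therefore cannot speak for real lists, whose members may vary together. For stage comparisons each fit was repeated within a library-number series, R8 or R10. With 1 R10 library at E18.5 in each population, that library is assumed to vary like the other groups. Alternatives tried were RLE factors, no expression filter, DESeq2 1.42.0, fits with the compared groups alone, a 2-fold threshold, leaving out each replicate, blocks of adjacent library numbers, the series as a covariate and the E18.5 libraries of R10 left out. A further 2 settings were added after seeing the data: E18.5 libraries of R8 left out, and counts divided by 2. Sample labels were also permuted among the compared groups. No count column was left unused.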

Results

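Mouse C57Bl/6 embryos from time-mated females, with the day of the plug taken as E0.5, gave sorted brain macrophages at 6 stages from E10.5 to E18.5. Each sorted sample was labelled as microglia, the macrophages of the brain parenchyma, or as border-associated macrophages (BAM), which live in the membranes and spaces around it. The microglia groups held 4, 3, 3, 2, 3 and 4 libraries in order of stage (n = 19), and the BAM groups held 4, 3, 3, 3, 3 and 4 (n = 20). RNA came from the PicoPure kit, and 2 ng of total RNA with a median integrity number of 7.7 entered a modified SMART-seq2 protocol with Nextera XT libraries and paired-end reads. The labels do not say which surface markers defined the sort gates or whether replicates came from separate litters, so every p-value measures only the spread between these samples. Of 53379 genes in the count table, 22061 were tested.

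Library names fell into 2 numbered series: 23 libraries of series R8 held 10.7 to 24.3 M counts and 16 of series R10 held 20.6 to 47.2 M. All E10.5 and E11.5 libraries and 1 E18.5 library of each population belonged to R10 and every other library to R8, so many stage results are also given within a single series. Among the 500 most variable genes the first principal component held 64.7% of the variance and set all E10.5 and E11.5 libraries, which are of R10, apart from all later ones. The second held 13.08% and placed all microglia on its positive side (6.133 to 29.3) and all BAM on the other. A simulation with added changes of known size recovered 42% of 2-fold and 69% of 4-fold changes at E10.5, and 37% and 62% at E14.5, where microglia had 2 libraries. For the mean over stages it recovered 76% and 92%.

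**Figure D1:**
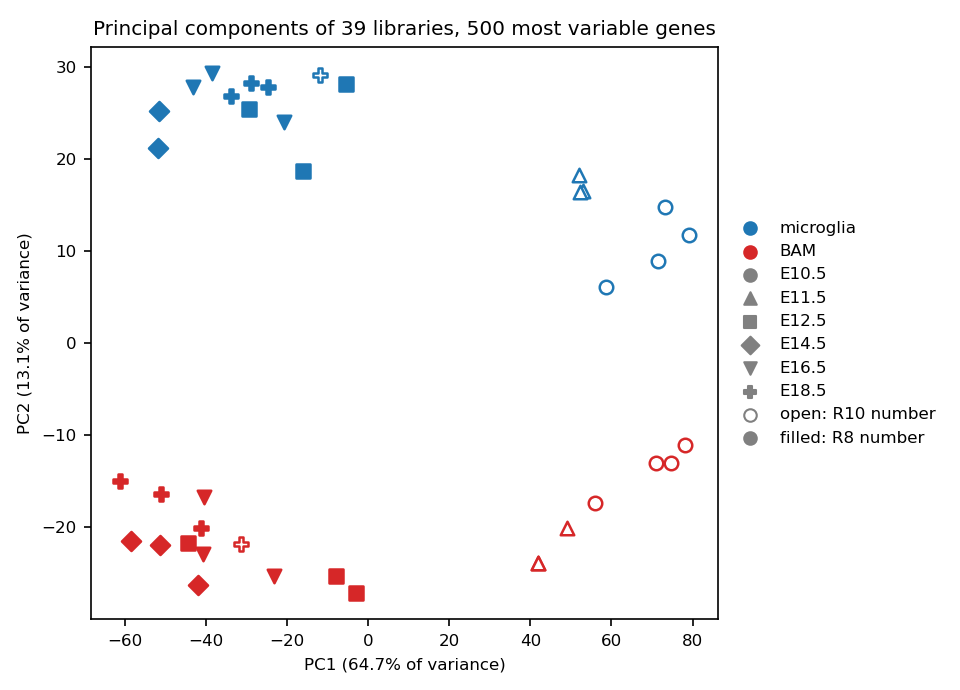
The first 2 principal components of the 39 libraries, coloured by population, with shapes for stage and open symbols for series R10. The second component separated microglia from BAM at every stage.

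To find genes that separated the populations throughout development, BAM (n = 20) were compared with microglia (n = 19) as the mean over the 6 stages. Genes are ranked by fold among called genes with an average log2 CPM of at least 4, here and below. Lyve1, a hyaluronan receptor of perivascular macrophages on chromosome 7 (110850607 to 110863239, GRCm38), was the gene most raised in BAM at log2 7.01 ± 0.35 (adjusted p = 6.36e-18). Spint1, an inhibitor of membrane serine proteases, was lowest in BAM among genes with more than 3 counts in every group, at log2 -5.14 ± 0.19 (adjusted p = 8.05e-22). Of the tested genes, 3030 were higher and 3199 lower in BAM, and 2159 of these 6229 differed at least 2-fold.

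After Lyve1, the genes most raised in BAM were the haemoglobin scavenger receptor Cd163 (5.01 ± 0.39), the platelet chemokine Pf4 (4.89 ± 0.34) and the galactose lectin Mgl2 (4.74 ± 0.27). Cd4 came next in rank, with a group at 0 counts and therefore no fold given, and it lost its call without BAM E10.5 replicate 3. Then followed the natriuretic peptide receptor Npr1 (4.09 ± 0.21), the lectin Clec10a (4.06 ± 0.27), the coagulation factor chain F13a1 (3.90 ± 0.20), the ficolin Fcna (3.86 ± 0.19) and the growth factor Bmp2 (3.76 ± 0.25). In the other direction Itgax, the integrin alpha chain of complement receptor 4, had 2 counts in each of 2 BAM groups, and at E18.5 it was lower in BAM by log2 -5.28 ± 0.71. Plxdc1, an endothelial type receptor, ranked second with a group at 0. Below Spint1 came the protease inhibitor Serpine2 (-4.82 ± 0.18), the cytokine Il1a (-4.81 ± 0.28), the integrin ligand Npnt (-4.76 ± 0.23), the matrix glycoprotein Olfml3 (-4.72 ± 0.14), the cytokine Il1b (-4.70 ± 0.41), the junction protein F11r (-4.69 ± 0.18) and the inhibitory receptor Pilra (-4.66 ± 0.25).

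The microglia core list, chosen beforehand as known markers and so no independent evidence of direction, held 22 of 25 genes lower in BAM, 0 higher and 3 not called, and 22 lower and 1 higher adjusted over the list alone (camera adjusted p = 1.02e-62). Within it Tmem119, a membrane protein of microglia, was lower by -3.94 ± 0.11 and the Golgi protein Golm1 by -2.69 ± 0.08. The purinergic receptor P2ry12 (-2.38 ± 0.08), the zinc finger factors Sall1 (-4.62 ± 0.31) and Sall3 (-3.86 ± 0.24), the lectin Siglech (-2.68 ± 0.10) and the fractalkine receptor Cx3cr1 (-1.08 ± 0.06) also were lower. Of 27 BAM core genes 22 were higher, 1 lower and 4 not called, with the same counts adjusted over the list alone (adjusted p = 1.87e-38). Its members with the smallest p were the collectin Colec12 (3.60 ± 0.11), the growth factor binder Igfbp4 (2.51 ± 0.09), the clearance receptor Stab1 (1.86 ± 0.08) and the endocytic adaptor Dab2 (2.95 ± 0.13). Mrc1, which encodes the mannose receptor CD206 and whose difference would be the gate's own if it was sorted on, was higher by 3.07 ± 0.14. The lipid carrier Apoe was not called (0.01 ± 0.11).

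Iron and haem handling was raised in BAM, with 10 of 12 genes higher and 1 lower by either adjustment (camera adjusted p = 1.73e-09). Its leading members were the haem transporter Slc48a1 (0.95 ± 0.05), the biliverdin reductase Blvrb (2.18 ± 0.13) and the iron exporter Slc40a1 (1.84 ± 0.12). Scavenger and endocytic receptors held 10 higher, 6 lower and 4 not called by either adjustment (adjusted p = 0.000889, and adjusted p = 0.0559 with an estimated correlation). This list shares Mrc1, Cd163, Stab1, Colec12 and Lyve1 with the BAM core list, all higher in BAM at every stage. Those members are no independent evidence, here and below. Interferon response genes held 12 higher, 2 lower and 8 not called, 13 and 3 adjusted over the list alone (adjusted p = 0.000219, but adjusted p = 0.225 with an estimated correlation). They were led by the oligoadenylate synthetases Oas2 (1.89 ± 0.14) and Oas1a (1.24 ± 0.12). DNA replication held 10 higher and 1 lower of 20 (adjusted p = 0.0139, but adjusted p = 0.39 with an estimated correlation). The licensing factor Cdc6 stood at 0.65 ± 0.08. Mitosis genes held 6 higher and 1 lower of 20 by either adjustment and did not move as a set (adjusted p = 0.286).

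Microglia were higher in TGF-beta signalling, where 10 of 16 genes were lower in BAM and 2 higher, 12 and 2 adjusted over the list alone (camera adjusted p = 4.68e-10). Among them were the repressor Skil (-2.87 ± 0.11), the receptor Tgfbr1 (-2.79 ± 0.13), the activating integrin Itgb5 (-1.88 ± 0.09) and the target Pmepa1 (-3.41 ± 0.21). Of 10 MHC class II genes 7 were lower in BAM and none higher by either adjustment (adjusted p = 4.6e-08). Among the lower ones were the peptide-loading chaperone genes H2-DMa (-3.83 ± 0.20), H2-DMb1 (-2.27 ± 0.14) and H2-DMb2 (-2.90 ± 0.25), while the presenting chain H2-Aa was not called (adjusted p = 0.563). Lysosome genes held 11 lower, 1 higher and 10 not called, 11 and 2 adjusted over the list alone (adjusted p = 3.51e-08, and adjusted p = 0.0667 with an estimated correlation). Leading members were the proteases Ctss (-2.07 ± 0.09) and Ctsd (-1.29 ± 0.06). Immediate early and heat shock genes held 9 lower and 3 higher of 20, 10 and 4 adjusted over the list alone (adjusted p = 0.000889, but adjusted p = 0.39 with an estimated correlation). The stimulus-induced factor Egr1 stood at -1.71 ± 0.14 and Egr2 at -2.04 ± 0.17. Glycolysis held 11 lower and 3 higher of 18 by either adjustment (adjusted p = 0.000409, but adjusted p = 0.207 with an estimated correlation). The hexokinase Hk2 stood at -0.97 ± 0.07. Cholesterol synthesis held 10 lower and 1 higher of 20, 11 and 1 adjusted over the list alone (adjusted p = 0.0308, but adjusted p = 0.374 with an estimated correlation). The reductase Dhcr7 stood at -0.71 ± 0.08.

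Several sets held genes on both sides. Complement had 5 higher and 7 lower of 14, 5 and 8 adjusted over the list alone (camera adjusted p = 0.282). The receptor chain Itgam stood at -2.34 ± 0.08 and the anaphylatoxin receptor C5ar1 at 1.71 ± 0.09. Cytokines and chemokines had 10 higher and 9 lower of 22, 10 and 10 adjusted over the list alone (adjusted p = 0.653). The growth factor Csf1 stood at -3.56 ± 0.14 against the chemokines Ccl7 (2.91 ± 0.16) and Ccl24 (3.22 ± 0.21). Macrophage transcription factors had 7 higher and 8 lower of 21, 7 and 9 adjusted over the list alone (adjusted p = 0.48). Etv1 stood at 1.73 ± 0.09. Haematopoietic progenitor genes had 2 higher and 2 lower of 11 by either adjustment (adjusted p = 0.282). The stem cell antigen Cd34 stood at -3.69 ± 0.17.

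Markers of other cells were measured beside these. Monocyte markers had 4 lower and none higher of 10 by either adjustment (camera adjusted p = 0.0499, but adjusted p = 0.299 with an estimated correlation). The chemokine receptor Ccr2 stood at -3.82 ± 0.36 and Plac8 at -3.04 ± 0.32. Erythroid genes had 7 lower and none higher of 11 by either adjustment (adjusted p = 0.0268, but adjusted p = 0.368 with an estimated correlation). The globin Hba-a1 stood at -0.98 ± 0.15. Granulocyte and mast cell markers had 2 higher of 9 (adjusted p = 0.207). The gelatinase Mmp9 stood at 3.06 ± 0.26. Endothelial markers had 1 higher and 1 lower of 12, the angiogenic factor Egfl7 (1.53 ± 0.14) and the adhesion receptor Pecam1 (-1.59 ± 0.13). Neural markers had 1 higher and 1 lower of 14, the growth cone protein Gap43 (0.90 ± 0.17) and the filament Nes (-2.01 ± 0.12). Mesenchymal and mural markers had 1 higher and 1 lower of 12, and 0 higher and 1 lower adjusted over the list alone, while lymphoid markers had 2 lower of 3, too few for the set test.

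To follow when the differences arose, BAM were compared with microglia at each stage. At E10.5 (n = 4 and 4) 512 genes were higher and 477 lower in BAM, and 578 of these 989 differed at least 2-fold. The membrane protein gene Ms4a14 led with 85.5 times the microglial count (15 to 3410, counting interval). Next were Lyve1 (5.65 ± 0.64), Cd163 (4.93 ± 1.37), the axon guidance ligand Sema6d (4.82 ± 0.38) and the kinase Dclk1 (4.18 ± 0.92). In the other direction Itgax had 120 times the BAM count in microglia (32.9 to 999). Then came the lipid flippase Atp8a2 (-4.64 ± 0.71), Plxdc1 (-4.10 ± 1.01), the glycoprotein Gpnmb (-3.70 ± 0.80) and the matrix protein Sparc (-3.30 ± 0.37). Microglia core genes already had 12 lower and 3 higher of 25, 17 and 4 adjusted over the list alone (camera adjusted p = 2e-19). BAM core genes had 15 higher and 1 lower of 27, 17 and 1 adjusted over the list alone (adjusted p = 2.34e-26). Iron and haem handling (7 higher of 12, adjusted p = 1.15e-13), TGF-beta signalling (5 lower of 16, adjusted p = 1.28e-05) and MHC class II (5 lower of 10, adjusted p = 4.99e-09) differed at this first stage too. With only the compared groups in the fit 469 genes were called and Ms4a14, Cd163, Dclk1, Plxdc1 and Gpnmb lost their calls (adjusted p = 0.149, 0.156, 0.344, 0.441 and 0.0657). The log2 values of Cd163, Dclk1, Plxdc1 and Gpnmb stayed close, at 4.86, 4.26, -3.98 and -3.67. Cd163 also lost its call without any of 5 single libraries, Ms4a14 without BAM replicate 4 and Plxdc1 without microglia replicate 3.

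At E11.5 (n = 3 and 3) 626 genes were higher and 844 lower in BAM, 876 at least 2-fold. Tnfsf18, a costimulatory ligand with no microglial count, was at least 49-fold higher. Next were Lyve1 (6.02 ± 0.74), the gelatinase Mmp9 (3.95 ± 0.65), the phosphatase Ptprk (3.76 ± 0.55) and Mgl2 (3.49 ± 0.58). Plxdc1 was at least 156-fold and the differentiation gene Ndrg2 at least 28.7-fold lower, and after them stood Sall1 (-6.56 ± 0.90), Npnt (-5.92 ± 0.61) and Serpine2 (-5.81 ± 0.48). Ndrg2 lost its call with the compared groups alone (adjusted p = 0.201) and without any of 4 single libraries. At E12.5 (n = 3 and 3) 908 were higher and 976 lower, 1072 at least 2-fold. Lyve1 (6.50 ± 0.75), Npr1 (4.36 ± 0.51), Cd163 (3.97 ± 0.87), Mgl2 (3.89 ± 0.59) and the lipid enzyme Enpp2 (3.58 ± 0.43) led in BAM. Itgax had 877 times the BAM count in microglia (242 to 7250), followed by Il1a (-7.98 ± 0.84), Il1b (-7.88 ± 1.18), Spint1 (-7.59 ± 0.54) and Serpine2 (-6.82 ± 0.50). MHC class II genes were lower in BAM at E12.5 in 8 of 10 cases (adjusted p = 1.03e-12). At E10.5 and at E11.5 it was 5 of 10, or 7 adjusted over the list alone, and these counts were not tested between stages. DNA replication genes were higher at E12.5 in 12 of 20, 14 adjusted over the list alone (adjusted p = 1.12e-09).

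At E14.5, with 3 BAM and 2 microglia libraries, 866 genes were higher and 718 lower in BAM, 1011 at least 2-fold. Lyve1 (7.65 ± 0.96), Tnfsf18 (5.91 ± 0.72), the protease Adam33 (5.26 ± 0.78), Mgl2 (5.18 ± 0.75) and Npr1 (4.97 ± 0.62) led in BAM. In microglia Pilra (-6.05 ± 0.73), Itgax (-5.97 ± 0.93), Spint1 (-5.91 ± 0.50), Olfml3 (-5.81 ± 0.39) and F11r (-5.40 ± 0.47) led. Interferon response genes had 8 higher and none lower of 22, 12 higher adjusted over the list alone (camera adjusted p = 8.27e-08, and adjusted p = 0.0631 with an estimated correlation). Without microglia replicate 1 the E14.5 calls dropped to 832. At E16.5 (n = 3 and 3) 1564 were higher and 1488 lower, 1637 at least 2-fold. Lyve1 (7.66 ± 0.80), Mgl2 (6.68 ± 0.68), Pf4 (6.54 ± 0.84), Clec10a (5.99 ± 0.69) and F13a1 (5.85 ± 0.50) were highest in BAM. Itgax (-5.11 ± 0.82), the orphan receptor Gpr35 (-5.00 ± 0.73), Pilra (-4.82 ± 0.64), Spint1 (-4.71 ± 0.45) and F11r (-4.60 ± 0.44) were lowest. Mitosis genes had 8 higher of 20 in BAM at E16.5, 13 adjusted over the list alone (adjusted p = 1.44e-05, but adjusted p = 0.172 with an estimated correlation).

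At E18.5 (n = 4 and 4) 1478 genes were higher and 1930 lower in BAM, 1732 at least 2-fold. Lyve1 (8.59 ± 0.72), Cd163 (8.14 ± 0.83), Pf4 (7.57 ± 0.77), F13a1 (6.72 ± 0.45) and the G protein regulator Rgs18 (6.71 ± 0.58) led in BAM. Itgax (-5.28 ± 0.71), Spint1 (-4.82 ± 0.40), Il1a (-4.69 ± 0.58), the fructose transporter Slc2a5 (-4.52 ± 0.28) and the chemokine receptor Cxcr2 (-4.46 ± 0.50) led in microglia. Microglia core genes had 23 lower of 25, 24 adjusted over the list alone (camera adjusted p = 8.18e-65). BAM core genes had 24 higher of 27 by either adjustment (adjusted p = 2.69e-59). Lysosome genes had 13 lower of 22, 15 lower and 1 higher adjusted over the list alone (adjusted p = 4.22e-15). Ctsd stood at -2.03 ± 0.12 and the protease Ctsl at -2.20 ± 0.16. Mitosis genes now had 13 lower of 20, 15 adjusted over the list alone (adjusted p = 2.84e-07, but adjusted p = 0.0868 with an estimated correlation). The checkpoint kinase Bub1 stood at -1.23 ± 0.17. DNA replication genes, higher in BAM for the mean over stages, had 0 higher and 6 lower of 20 within series R8 at E18.5 (median log2 -0.363). Within series R8 alone (n = 3 and 3) 2602 genes were called at E18.5, and Lyve1 stood at 8.11, Cd163 at 7.78 and Spint1 at -4.72. Between the single R10 libraries Itgax and Bub1 were not called, at log2 values of -5.15 and -1.05 (adjusted p = 0.0515 and 0.0595).

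**Figure D2:**
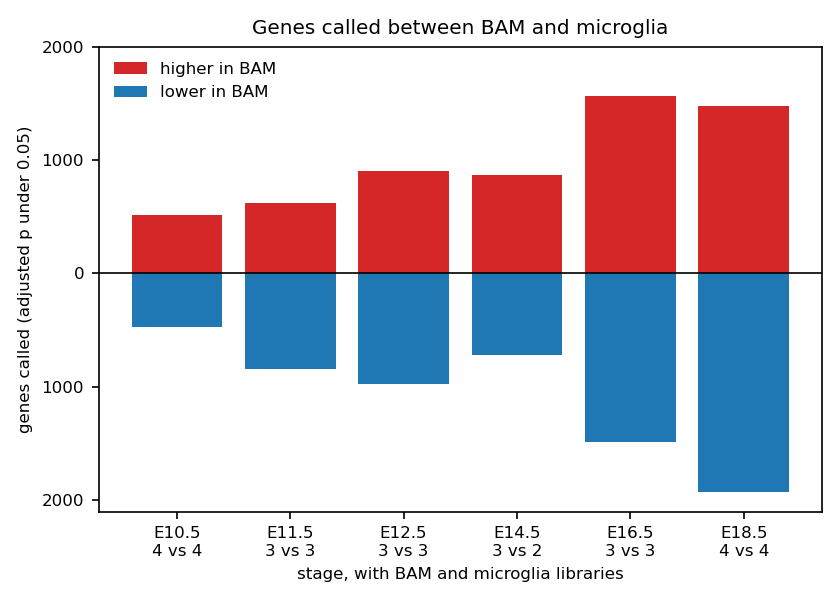
Number of genes higher and lower in BAM than in microglia at each stage.

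Across stages, 189 genes were higher and 209 lower in BAM at all 6. Of the genes called at E10.5, 290 stayed higher and 277 stayed lower at E18.5, against 34.3 and 41.7 expected from the 2 sets by themselves, while 35 and 20 turned direction. Lyve1 and Spint1 were among the genes called at every stage. Mrc1 in BAM stood at 3701 ± 624 CPM at E10.5 and 9009 ± 857 at E18.5, and in microglia at 1108 ± 461 and 574.7 ± 61.3. Tmem119 in microglia stood at 241.9 ± 57.2 and 1068 ± 95.8, and in BAM at 46.31 ± 21.1 and 63.86 ± 5.63.

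**Figure D3:**
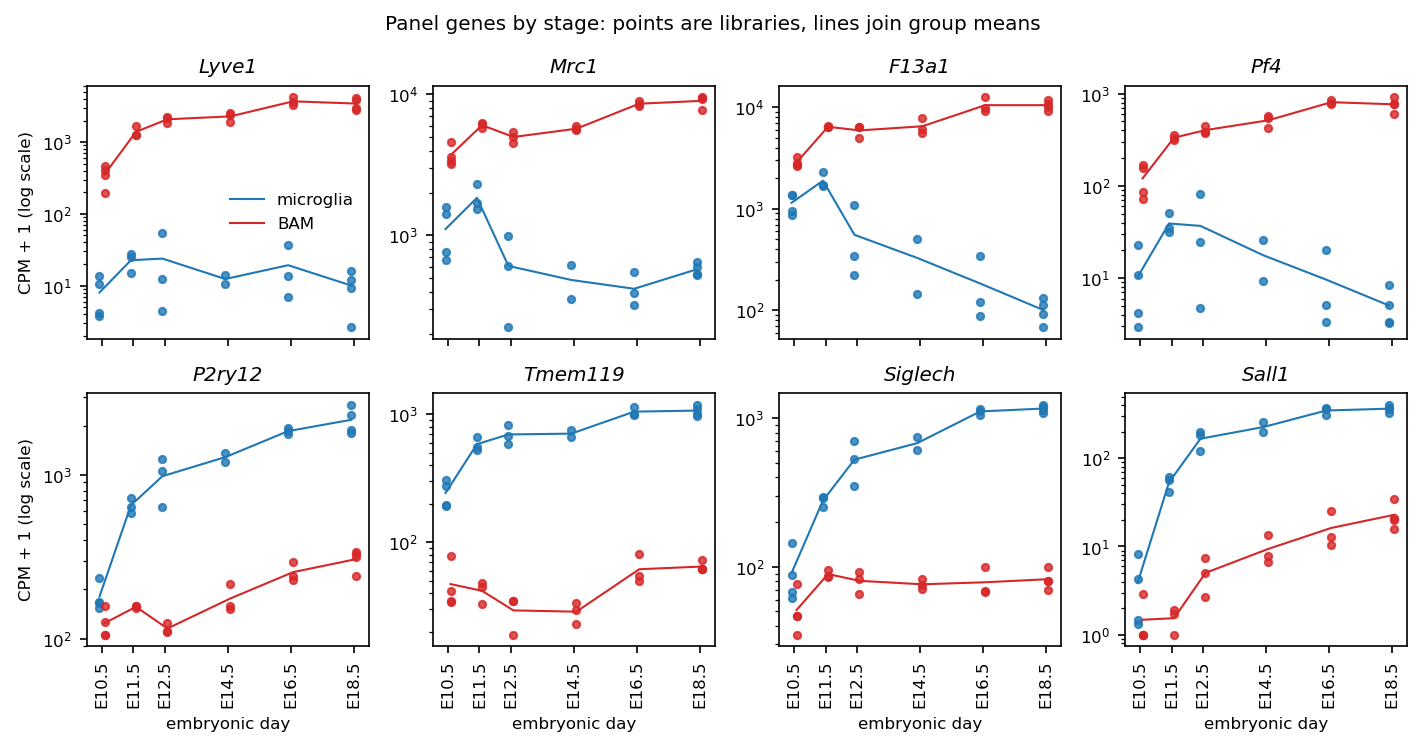
CPM plus 1 of 8 panel genes in each library by stage, with lines joining group means.

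To see how microglia matured, those at E18.5 (n = 4) were compared with those at E10.5 (n = 4). Ptgds, which encodes a prostaglandin synthase, had no count at E10.5 and was at least 1010-fold higher at E18.5. Rgs18, a regulator of G protein signalling, was the most lowered gene with an average log2 CPM of at least 4, at log2 -6.71 ± 0.58 (adjusted p = 2.91e-11). Of the tested genes 4604 were higher and 3184 lower at E18.5, and 4742 of these 7788 changed at least 2-fold. The median gene lay 0.292 above zero in this comparison and 0.291 in the BAM one. Genes at or above log2 CPM of 4 lay -0.103 and -0.118 from zero, so the upward shift lay among sparsely counted genes. That shift also went in part with the series. With the R8 libraries of E18.5 left out both medians were 0, and with the series as covariate 0.0997 and 0.146. Calls were not split by level. Within series R10, where 1 library stood for E18.5, 3743 genes were called, 2053 higher and 1690 lower, and 3587 of the 7788 pooled calls were among them. The E10.5 libraries are the same in both fits.

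After Ptgds came Ttr, a thyroid hormone carrier of the choroid plexus, at least 672-fold higher, and Tnfsf18 with 421 times its E10.5 count (116 to 3490, counting interval). Whether Ptgds, Ttr and the other genes raised here, Dclk1, Mapt and Vtn among them, came from microglia or from RNA of other cells was not tested. Cd4 was at least 42.7-fold higher but not called within R10 (adjusted p = 0.0996), and Dclk1 rose by 7.43 ± 0.89 (6.56 within R10). Ms4a14 had 262 times its count (46.4 to 10400), and the microtubule protein Mapt rose by 7.32 ± 0.51 (6.84). The inhibitory receptor Lag3 rose by 7.28 ± 0.31 (7.52), the adhesion protein Vtn by 7.27 ± 0.94 (6.51) and the secreted phosphoprotein Spp1 by 7.21 ± 0.37 (7.72). Below Rgs18 (-5.89 within R10) the embryonic globin Hbb-y changed by -6.60 ± 0.62 (-6.18), the mRNA binder Igf2bp1 by -5.92 ± 0.19 (-5.98) and the adhesion protein Emb by -5.29 ± 0.23 (-5.22). The sialic acid hydroxylase Cmah changed by -3.98 ± 0.41 (-2.85) and the endothelin receptor Ednrb by -3.56 ± 0.27 (-3.62). F13a1 (-3.52 ± 0.39, and -3.69), the asparagine synthetase Asns (-3.51 ± 0.20, and -3.25), the matrix protein Emilin2 (-3.44 ± 0.21, and -3.54) and the scaffold Ahnak (-3.42 ± 0.25, and -3.47) completed the 10.

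Microglia core genes rose in 24 of 25 cases with none lower by either adjustment (camera adjusted p = 2.42e-47), and in 22 within R10. Fcrls, an Fc receptor-like gene, rose by 3.31 ± 0.11, the crystallin Crybb1 by 6.87 ± 0.34, P2ry12 by 3.59 ± 0.18 and Siglech by 3.70 ± 0.24. Their summed level went from 5583 ± 778 to 33430 ± 3250 CPM. Lysosome genes rose in 20 of 22 cases (adjusted p = 3.88e-34) and in 20 within R10. They were led by Ctsd (3.24 ± 0.13), the progranulin gene Grn (2.47 ± 0.11) and the protease Lgmn (2.22 ± 0.10). Complement had 11 higher and 1 lower of 14 (adjusted p = 2.1e-05; 9 and 1 within R10). The C1q chain C1qa stood at 3.22 ± 0.26. TGF-beta signalling had 9 higher and 1 lower of 16, 11 and 1 adjusted over the list alone (adjusted p = 0.00357; 5 and 0 within R10). Itgb5 stood at 1.52 ± 0.19.

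Interferon response genes rose in 20 of 22 cases (camera adjusted p = 5.32e-05, but adjusted p = 0.132 with an estimated correlation), yet within R10 only 4 were higher and 1 lower. The antiviral gene Rsad2 stood at 4.86 ± 0.63 (4.56 within R10), while Oas2 (1.74 ± 0.30 pooled) was not called there (0.99, adjusted p = 0.09). Cytokines and chemokines had 12 higher and 1 lower of 22, 13 and 1 adjusted over the list alone (adjusted p = 8.2e-05, but adjusted p = 0.12 with an estimated correlation; 8 and 0 within R10). Csf1 stood at 5.28 ± 0.34 and the chemokine Cxcl16 at 3.82 ± 0.36. MHC class II had 6 higher of 10 (adjusted p = 0.00338, and adjusted p = 0.0991 with an estimated correlation; 3 within R10). H2-DMb1 stood at 3.42 ± 0.31. Scavenger and endocytic receptors had 11 higher and 4 lower of 20 (adjusted p = 0.000865, and adjusted p = 0.0614 with an estimated correlation; 7 and 0 within R10). The Fc receptor Fcgr2b stood at 3.47 ± 0.21.

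Cell division genes fell. All 20 DNA replication genes were lower by either adjustment and within R10 (camera adjusted p = 3.72e-31), among them the helicase subunit Mcm5 (-1.74 ± 0.12), the histone chaperone Chaf1a (-1.94 ± 0.14) and Cdc6 (-2.41 ± 0.18). Of the mitosis genes 19 of 20 fell (adjusted p = 6.32e-20; 16 within R10), among them the kinase Aurka (-1.84 ± 0.15). Cholesterol synthesis had 18 lower of 20 (adjusted p = 2.52e-09; 8 within R10). The isomerase Idi1 stood at -2.51 ± 0.26. Glycolysis had 12 lower and 2 higher of 18, 12 and 3 adjusted over the list alone (adjusted p = 5.25e-08; 7 and 1 within R10). The phosphofructokinase Pfkp stood at -2.66 ± 0.19. Haematopoietic progenitor genes had 5 lower and 1 higher of 11 (adjusted p = 0.00891, and adjusted p = 0.0503 with an estimated correlation; 3 and 1 within R10). The platelet integrin Itga2b stood at -4.37 ± 0.79. BAM core genes had 10 higher and 8 lower of 27 (adjusted p = 0.767). Apoe stood at 2.51 ± 0.26 and the lectin Clec12a at -2.93 ± 0.26. Immediate early genes, iron handling and the macrophage transcription factors were not called as sets (adjusted p = 0.0923, 0.382 and 0.126).

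Markers of other cells were counted in the same libraries. Mesenchymal and mural markers had 11 higher of 12 (camera adjusted p = 5.38e-05, and adjusted p = 0.0774 with an estimated correlation; 7 within R10). The collagen Col1a1 stood at 6.04 ± 0.71. Neural markers had 10 higher of 14 (adjusted p = 0.000143, but adjusted p = 0.141 with an estimated correlation; 6 within R10). The radial glia protein Fabp7 stood at 6.68 ± 0.76. Endothelial markers had 6 higher and 1 lower of 12 (2 and 2 within R10), and granulocyte and mast cell markers 3 higher and 1 lower of 9 (1 and 0). Erythroid genes had 5 higher and 3 lower of 11 (5 and 4) and monocyte markers 3 lower of 10 (1). None of these was called as a set (adjusted p = 0.275, 0.564, 0.592 and 0.144), and none of 3 lymphoid genes was called. Globin genes switched type, as the embryonic Hbb-y went from 33.85 ± 24.3 to 0.3724 ± 0.313 CPM and the adult Hbb-bs from 0.5969 ± 0.42 to 83.19 ± 22.5.

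For an interval that series R8 can cover by itself, microglia at E18.5 were set against E12.5 (n = 4 and 3). The pooled fit, which includes the R10 library of E18.5, called 884 genes higher and 604 lower, 585 at least 2-fold. Within R8, without that library, 1021 were called. Without microglia E12.5 replicate 3 the calls dropped from 1488 to 701. Ptgds rose by 7.47 ± 1.12, Gpnmb by 5.10 ± 0.79, Tnfsf18 by 4.13 ± 0.56, Ndrg2 by 4.08 ± 0.88 and Spp1 by 3.94 ± 0.36, all called within R8. Hbb-y changed by -10.00 ± 0.67, Rgs18 by -4.28 ± 0.58, Igf2bp1 by -4.01 ± 0.18, the noncoding transcript Miat by -3.77 ± 0.72 and Pf4 by -3.15 ± 0.69. With the single R10 library for E18.5, Ndrg2, Miat and Pf4 were not called, at log2 values of 3.33, -4.43 and -4.03 (adjusted p = 0.13, 0.0771 and 0.113), and Pf4 was not without microglia E12.5 replicate 3. Microglia core genes rose in 16 of 25 cases, 21 adjusted over the list alone (camera adjusted p = 1.6e-31; 14 within R8), and lysosome genes in 17 of 22 (adjusted p = 4.53e-35; 16 within R8). None of the 20 mitosis genes and none of the 22 interferon genes was called between E12.5 and E18.5 (camera adjusted p = 0.475 and 0.168). Summed mitosis genes stood at 2453 ± 48.5 CPM at E12.5, 1471 ± 123 at E16.5 and 2393 ± 304 at E18.5. BAM core genes had 10 lower and 2 higher of 27 (adjusted p = 2.8e-05, but adjusted p = 0.235 with an estimated correlation; 9 and 1 within R8). Haematopoietic progenitor genes had 3 lower of 11 (adjusted p = 2.57e-05; 3 within R8) and complement 5 higher of 14 (adjusted p = 1.36e-05). Among markers of other cells, erythroid genes had 4 lower and 1 higher of 11 (adjusted p = 9.03e-09, and adjusted p = 0.0118 with an estimated correlation; 4 and 1 within R8). Neural markers had 2 lower and 1 higher of 14 (adjusted p = 0.0422, but adjusted p = 0.554 with an estimated correlation). DNA replication (3 lower), glycolysis (3 higher) and immediate early genes (4 higher) were called as sets at the preset correlation alone.

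To see how BAM matured, those at E18.5 (n = 4) were compared with those at E10.5 (n = 4). Ptgds was at least 3050-fold higher, having had no count at E10.5, and the Fc receptor Fcgr2b, which restrains antibody responses, rose by log2 7.43 ± 0.25 (adjusted p = 3.26e-21). Of the tested genes 5030 were higher and 3265 lower, and 5407 of these 8295 changed at least 2-fold. Within R10, 4212 genes were called, and 4028 of the 8295 pooled calls were among them.

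After Ptgds came Tnfsf18, at least 2830-fold higher, the pericyte gene Rgs5, at least 2390-fold, Cd163 at 9.30 ± 0.87 (9.46 within R10) and Ttr at 9.29 ± 1.24 (5.33). Rgs5 is a member of the mesenchymal and mural list. Whether Ptgds, Rgs5, Ttr and the other genes raised here, Vtn among them, came from BAM or from RNA of other cells was not tested. Also raised were Vtn at 8.43 ± 0.96 (6.95), Adam33 at 8.34 ± 0.65 (8.26), the carbonyl reductase Cbr2 at 7.68 ± 0.65 (7.21) and Fcgr2b (7.39). Among lowered genes were Hbb-y (-6.30 ± 0.60, and -6.60 within R10), the phosphatase Ptpn7 (-4.83 ± 0.38, and -3.70), the amino acid transporter Slc43a1 (-4.29 ± 0.50, and -6.04), Igf2bp1 (-3.85 ± 0.17, and -3.67) and the lipoprotein lipase Lpl (-3.60 ± 0.13, and -3.52). Then followed the serine synthesis enzyme Phgdh (-3.58 ± 0.18, and -4.21), the tropomyosin Tpm2 (-3.43 ± 0.26, and -3.91), BC035044 (-3.37 ± 0.21, and -3.34), the immunoglobulin heavy chain Ighm (-3.31 ± 0.13, and -3.55) and the tetraspanin Tspan32 (-3.08 ± 0.23, and -2.71).

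BAM core genes rose in 24 of 27 cases with 1 lower by either adjustment (camera adjusted p = 1.42e-16; 23 within R10), led by the matrix protein Tgfbi (1.92 ± 0.11), Cbr2 and Colec12 (2.29 ± 0.21). Mrc1 rose by 1.28 ± 0.27. Interferon response genes rose in 21 of 22 cases by either adjustment (adjusted p = 1.44e-15) and in 20 within R10, led by Oas2 (4.19 ± 0.32) and Oasl2 (3.54 ± 0.30). Scavenger and endocytic receptors had 15 higher and 1 lower of 20 (adjusted p = 7.69e-09; 11 and 1 within R10). The HDL receptor Scarb1 stood at -1.38 ± 0.12. Microglia core genes also rose, 17 higher and 1 lower of 25, 18 and 2 adjusted over the list alone (adjusted p = 5.07e-09; 14 and 1 within R10). Among them were Lag3 (4.90 ± 0.29), Sparc (4.27 ± 0.39), Crybb1 (3.18 ± 0.29) and Olfml3 (3.20 ± 0.29). Lysosome had 15 higher and 1 lower of 22 (adjusted p = 7.88e-10; 13 and 1 within R10). Grn stood at 1.38 ± 0.10. Complement had 10 higher and 1 lower of 14 (adjusted p = 8.25e-05; 7 and 0 within R10). The classical pathway protease C2 stood at 5.05 ± 0.40. Macrophage transcription factors had 12 higher and 2 lower of 21 (adjusted p = 0.00745; 10 and 1 within R10). Bhlhe41 stood at 3.73 ± 0.28. MHC class II had 8 higher of 10 (adjusted p = 0.0013, and adjusted p = 0.055 with an estimated correlation; 5 within R10). H2-DMb1 stood at 3.03 ± 0.32.

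All 20 DNA replication genes fell by either adjustment and within R10 (camera adjusted p = 2.21e-42). Mcm5 stood at -2.33 ± 0.12 and the reductase subunit Rrm2 at -2.66 ± 0.16. Of the mitosis genes 19 of 20 fell (adjusted p = 1.9e-40; 19 within R10). Aurka stood at -2.56 ± 0.15 and Mki67 at -1.39 ± 0.17. Glycolysis had 11 lower and 2 higher of 18 (adjusted p = 3.01e-11; 11 and 1 within R10). The lactate dehydrogenase Ldha stood at -2.22 ± 0.13. Cholesterol synthesis had 15 lower of 20 (adjusted p = 2.21e-07; 12 within R10). The epoxidase Sqle stood at -2.33 ± 0.24. Cytokines, iron handling, TGF-beta signalling, haematopoietic progenitor and immediate early genes were not called as sets (adjusted p = 0.141, 0.348, 0.178, 0.75 and 0.981), although the transferrin gene Trf rose by 3.24 ± 0.17 and its receptor Tfrc changed by -2.61 ± 0.21. All 12 mesenchymal and mural markers rose (adjusted p = 1.31e-06; 8 within R10). The collagen Col3a1 stood at 4.38 ± 0.49. Neural markers had 9 higher and 1 lower of 14 (adjusted p = 0.000114, but adjusted p = 0.15 with an estimated correlation; 6 and 1 within R10). Fabp7 stood at 6.71 ± 0.74. Endothelial markers had 8 higher of 12 (adjusted p = 0.0282, but adjusted p = 0.288 with an estimated correlation), while within R10 only 3 were higher and 1 lower. Their sum in the R10 library of E18.5 was 110.7 CPM, against 109.8 in the highest E10.5 library and 210.8 to 404 in the R8 libraries. The claudin Cldn5 stood at 5.69 ± 0.91. Granulocyte and mast cell markers had 4 higher of 9, 5 adjusted over the list alone and 4 within R10, and were not called as a set (adjusted p = 0.0726). Their mast cell genes Cpa3, Tpsb2 and Cma1 were at least 236-fold, 201-fold and 128-fold higher.

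BAM at E18.5 were also set against E12.5 (n = 4 and 3), with 1156 genes higher and 1174 lower, 935 at least 2-fold, and 2006 called within R8. Without BAM E12.5 replicate 3 the calls dropped from 2330 to 1504. Ptgds (9.28 ± 1.19), the calcium channel Trpm2 (6.51 ± 0.52) and Cd163 (5.78 ± 0.83) rose most, Itgax had 59.6 times its E12.5 count (16.2 to 497), and the glucose-sensing factor Mlxipl rose by 4.81 ± 0.52. Hbb-y (-8.66 ± 0.63), Ighm (-3.40 ± 0.14), Lpl (-2.61 ± 0.13), Miat (-2.61 ± 0.69) and Ptpn7 (-2.61 ± 0.37) were most lowered. Miat lost its call without BAM E12.5 replicate 1 (adjusted p = 0.238). Over this interval 18 of 20 mitosis genes and all 20 DNA replication genes fell (camera adjusted p = 3.72e-31 and 5.8e-47), with 19 and 20 lower within R8. Only 1 of 22 interferon genes was called higher (adjusted p = 0.0241, but adjusted p = 0.438 with an estimated correlation; 1 within R8) in that interval. Macrophage transcription factors rose in 9 of 21 cases, 12 adjusted over the list alone (adjusted p = 7.03e-08; 9 within R8). Bhlhe41 stood at 3.67 ± 0.32. Sets also called higher at either correlation were microglia core (17 of 25 genes higher), BAM core (10 of 27), MHC class II (6 of 10), lysosome (13 of 22), complement (8 of 14), scavenger receptors (7, with 1 lower, of 20) and TGF-beta signalling (5 of 16). Cytokines (4 higher), glycolysis (8 higher and 4 lower) and immediate early genes (4 higher and 1 lower) were called at the preset correlation alone. Among markers of other cells, granulocyte and mast cell markers had 3 higher of 9 (adjusted p = 0.00495, and adjusted p = 0.0575 with an estimated correlation; 3 within R8). Endothelial markers had 3 higher of 12 (adjusted p = 0.0301, but adjusted p = 0.332 with an estimated correlation; 4 within R8). Erythroid genes had 4 lower and 1 higher of 11 (adjusted p = 0.00212, but adjusted p = 0.159 with an estimated correlation; 4 and 2 within R8).

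Many changes were common to both populations between E10.5 and E18.5, with 2900 genes higher in both (1050 expected from independent sets) and 2289 lower in both (471.2 expected). Lag3, Hbb-y and Igf2bp1 were among them.

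To find genes whose difference between the populations widened or narrowed with age, the change from E10.5 to E18.5 in BAM was set against that in microglia (n = 4 in each of the 4 groups). Rgs18, a regulator of G protein signalling at chromosome 1 (144752683 to 144775435), led the genes counted in every group at log2 7.82 ± 0.71 (adjusted p = 1.2e-09). It went from 38.26 ± 6.39 to 0.3316 ± 0.328 CPM in microglia and from 17.75 ± 3.29 to 38.5 ± 7.98 in BAM. The contrast called 679 genes higher and 784 lower, 1001 of these 1463 at least 2-fold, and 465 within R10. Permuting stage labels within each population gave a count this large in 3 of 40 draws, the real labels included. In the others at least 6 of 8 libraries of a population changed place, which carries the common stage effect into the contrast. These draws therefore decide nothing about chance, and the genes stand on their own tests.

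Rgs5 ranked first with a group at 0, and lost its call within R10 (adjusted p = 0.343) and without any of 8 single libraries. Behind Rgs18 (7.36 within R10) came F13a1 (5.39 ± 0.53, and 5.70), the DNA sensor family gene Ifi211 (5.04 ± 0.60, and 6.80) and the inflammasome gene Nlrc4 (4.79 ± 0.56, and 7.30). Then followed Adam33 (4.50 ± 0.92, and 5.32), Clec10a (4.17 ± 0.75, and 5.68), the collectin receptor Cd93 (4.12 ± 0.49, and 6.00), Cmah (4.02 ± 0.53, and 3.07) and the fatty acid receptor Cd36 (4.02 ± 0.49, and 3.75). Lower were the protease Adamts1 (-3.93 ± 0.58, and -4.38 within R10), Slc2a5 (-3.91 ± 0.35, and -4.56), the purinergic receptor-like P2ry10b (-3.74 ± 0.48, and -3.55), Csf1 (-3.73 ± 0.43, and -3.95) and Crybb1 (-3.69 ± 0.40, and -4.09). The ubiquitin ligase Rnf128 (-3.68 ± 0.51, and -3.67), Ighm (-3.44 ± 0.17, and -3.85), Slc43a1 (-3.39 ± 0.64, and -5.27), the potassium channel Kcnd1 (-3.33 ± 0.63, and -5.74) and the adhesion molecule Cadm1 (-3.27 ± 0.23, and -3.45) completed the 10. Adam33 turned to -1.72 without microglia E10.5 replicate 3.

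Both core lists moved apart. Microglia core genes had 15 lower of 25, 17 adjusted over the list alone (camera adjusted p = 1.84e-38; 13 within R10), with a median of -1.58. Fcrls stood at -2.38 ± 0.15, Siglech at -3.00 ± 0.31, P2ry12 at -2.29 ± 0.24 and Tmem119 at -1.68 ± 0.30. BAM core genes had 18 higher of 27, 21 higher and 1 lower adjusted over the list alone (adjusted p = 1.67e-30; 9 within R10), with a median of 2.52. Tgfbi stood at 2.52 ± 0.15, Colec12 at 2.60 ± 0.29, the membrane protein Ms4a6c at 2.40 ± 0.29, Mrc1 at 2.23 ± 0.38, Lyve1 at 2.94 ± 0.78 and Pf4 at 3.88 ± 0.88. Cd163 (3.20 ± 2.92), Sall1 (-1.58 ± 1.03) and Apoe (0.13 ± 0.34) were not called. Within R10 Mrc1, Pf4 and Tmem119 were not called either, at log2 values of 2.15, 4.95 and -1.86 (adjusted p = 0.0908, 0.124 and 0.0631), and Lyve1 was not with the R10 libraries of E18.5 left out (2.47, adjusted p = 0.0597) or without microglia E10.5 replicate 3. Lyve1 stood at 353.6 ± 118 and 3449 ± 637 CPM in BAM at the 2 stages and at 7.035 ± 4.83 and 9.047 ± 5.71 in microglia.

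Lysosome genes rose more in microglia, with 10 lower of 22 in the contrast, 13 adjusted over the list alone (camera adjusted p = 2.72e-17; 7 within R10), led by Ctsd (-2.20 ± 0.17), Ctsb (-1.56 ± 0.15) and Ctsl (-2.09 ± 0.22). Interferon response genes rose more in BAM, with 8 higher of 22, 9 adjusted over the list alone (adjusted p = 9.84e-10; 4 within R10), led by Oasl2 (2.52 ± 0.40) and Oas2 (2.45 ± 0.41). Mitosis genes fell further in BAM, with 5 lower of 20, 16 adjusted over the list alone (adjusted p = 2.98e-10; 1 within R10), led by Ccnb1 (-1.11 ± 0.22). DNA replication had 2 lower of 20, 3 adjusted over the list alone (adjusted p = 0.0012, but adjusted p = 0.26 with an estimated correlation; 1 within R10). Rrm2 stood at -1.02 ± 0.22. Haematopoietic progenitor genes had 2 higher of 11, 3 higher and 1 lower adjusted over the list alone (adjusted p = 0.000372; 1 higher within R10), with a median of 2.54, or 1.97 when members with a group at 0 stood at their bound.

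Cytokines and chemokines had 2 higher and 7 lower of 22, 2 and 9 adjusted over the list alone (camera adjusted p = 0.000372, but adjusted p = 0.203 with an estimated correlation; 0 and 4 within R10). The chemokine Ccl6 stood at -2.80 ± 0.29 and Ccl24 at 3.38 ± 0.59 (3.21 and adjusted p = 0.0976 within R10). Scavenger and endocytic receptors had 8 higher and 4 lower of 20, 8 and 5 adjusted over the list alone (adjusted p = 0.0012, and adjusted p = 0.0745 with an estimated correlation; 5 and 3 within R10). Fcgr2b stood at 3.96 ± 0.28 and the lipoprotein receptor Lrp1 at -1.78 ± 0.21. Immediate early and heat shock genes had 2 lower of 20 (adjusted p = 0.0208, but adjusted p = 0.545 with an estimated correlation; 1 within R10). Egr1 stood at -2.91 ± 0.42. MHC class II, complement, iron handling, TGF-beta signalling, macrophage transcription factors, glycolysis and cholesterol synthesis were not called as sets (adjusted p = 0.403, 0.867, 0.867, 0.095, 0.133, 0.128 and 0.312), and of the other-cell lists none was called.

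By direction in each population, genes with a higher contrast comprised 280 that rose in BAM alone, 152 that fell in microglia alone, 108 that rose in both, 89 that moved oppositely, 46 that fell in both and 4 called in neither. Genes with a lower contrast comprised 264 that rose in microglia alone, 186 that fell in BAM alone, 158 that rose in both, 97 that fell in both, 77 that moved oppositely and 2 called in neither. Rgs18 was among those that moved oppositely, at -6.71 ± 0.58 in microglia and 1.12 ± 0.41 in BAM (adjusted p = 0.0305), and Csf1 rose in microglia by 5.28 ± 0.34.

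**Figure D4:**
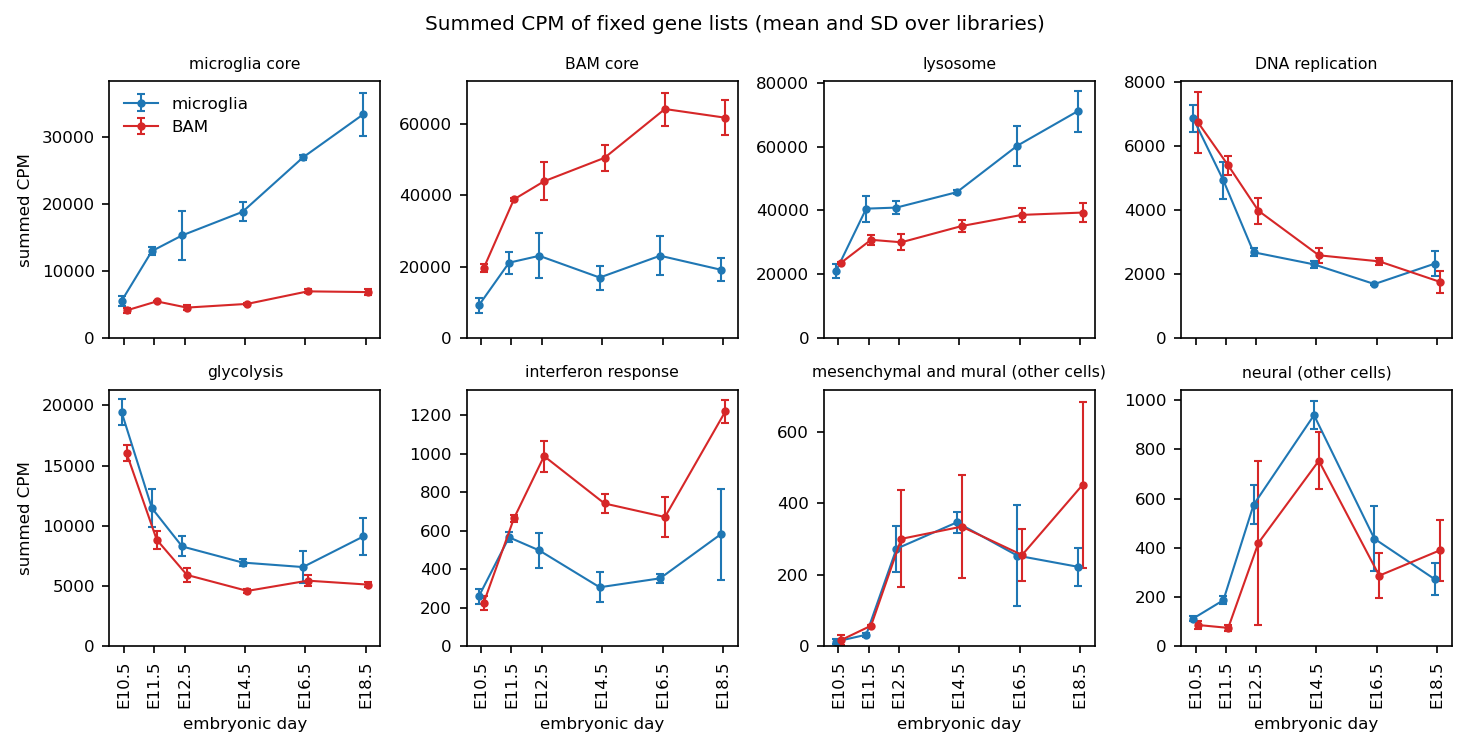
Summed CPM of 8 gene lists by stage, as mean and standard deviation over libraries.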

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

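The tests of RNA of other cells, of the median rise of microglia core genes in BAM, of regrouped libraries at E11.5 and of population labels permuted within stage were chosen after the results were seen.

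Single libraries stood far from the others in 13 of 180 groups tested, where chance gives about 1 in 20, or 9. In microglia at E10.5 the highest Cd163 was 0.2617 CPM (replicate 1) and the highest erythroid sum 160.6 (replicate 3). In microglia at E18.5 replicate 3 was highest in H2-Aa at 3.344, iron and haem genes at 5099 and monocyte markers at 462.5. Replicate 1, the R10 library that stands alone for E18.5 within that series, was highest in summed microglia core genes at 38260 and cholesterol synthesis genes at 727.6. In BAM at E10.5 the highest Sall1 was 1.916 and the lowest Ccr2 0.2129 (both replicate 1), and the lowest Mki67 457.1 (replicate 4). In BAM at E18.5 the lowest Mrc1 was 7733 and the lowest microglia core sum 6161 (both replicate 3), and the highest Tmem119 72.29 (replicate 4).

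The log2 difference, BAM minus microglia, was higher at E18.5 than at E10.5 for 679 genes and lower for 784, by a test of the difference itself. The genes so set apart were Rgs18 at 7.82, F13a1 at 5.39, Ifi211 at 5.04, Nlrc4 at 4.79, Adam33 at 4.50, Clec10a at 4.17, Cd93 at 4.12, Cmah at 4.02 and Cd36 at 4.02. In the other direction were Adamts1 at -3.93, Slc2a5 at -3.91, P2ry10b at -3.74, Csf1 at -3.73, Crybb1 at -3.69, Rnf128 at -3.68, Ighm at -3.44, Slc43a1 at -3.39, Kcnd1 at -3.33 and Cadm1 at -3.27. Among panel genes were Mrc1 at 2.23, Lyve1 at 2.94, Pf4 at 3.88, P2ry12 at -2.29, Tmem119 at -1.68, Siglech at -3.00 and Cx3cr1 at -1.23. List medians were -1.58 for microglia core, 2.52 for BAM core, -0.68 for mitosis, 2.54 for haematopoietic progenitor, 1.1 for interferon response and -0.542 for lysosome.

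Regrouping the libraries at random gave a count as large as the real one only for the real grouping itself, 1 of 35, at E10.5 (highest other 189), at E18.5 (5), and for E18.5 against E10.5 and E12.5 in microglia (462 and 424) and in BAM (1377 and 667), and 1 of 40 for the mean over stages (1). At E11.5, E12.5 and E16.5 the highest other of 10 groupings called 3, 1 and 0 genes, too few groupings to exclude chance. Libraries of E14.5 were not regrouped. For the population-by-stage contrast 3 of 40 draws with stage labels permuted within population were as large, the highest at 6869, and 3 of 40 with population labels permuted within stage, the highest at 2821. In the large draws at least 6 of 8 libraries of a side changed place, close to a full exchange, which carries effects common to both sides into the contrast. They decide nothing about chance for the count of 1463, and the median of the other draws was 0. If adjacent library numbers mark pairs, exchange within pairs alone leaves too few groupings at E10.5 and E18.5 to exclude chance.

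Neural and mesenchymal markers rose from E10.5 to E18.5 in both populations, as in Fabp7 and Col1a1, although with an estimated correlation only the mesenchymal set in BAM was called (adjusted p = 0.0403, against 0.0774 in microglia and 0.141 and 0.15 for the neural set). The series alone would not give a rise within R10, where the E18.5 library stood at least 1.6 times above the highest E10.5 library for both lists. That comparison rests on a single E18.5 library in each population. The same library stood below every R8 library of E18.5. Neural sums were 196.2 CPM against 241.5 to 336.9 in microglia, and 257.7 against 359.6 to 559 in BAM. Mesenchymal sums were 153.9 against 206.2 to 268.8 in microglia, and 222.3 against 307.2 to 736.4 in BAM. Part of the pooled rise may therefore go with the series. Transcripts of other cells in the sorted libraries may account for the rise. Deviations from the group means varied together, with mean correlations of 0.387 for neural and 0.304 for mesenchymal markers. Both were at percentile 100 of matched random lists, whose 95th percentiles were 0.0484 and 0.0608. Endothelial and erythroid lists also reached percentile 100. The random lists were matched on expression alone, and deviations at E18.5 hold the series, so this cannot tell other cells from another shared source. No table tells tissue fragments from macrophages that took up such cells.

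Many genes, among them Lag3 and Igf2bp1, changed between E10.5 and E18.5 in both populations. The series could not be the whole cause, since 63.9% of the calls or more stayed called in the same direction with series as a covariate. Depth could not be either, since 24% or more of the 3488 genes with log2 CPM of at least 6, where counts are ample, changed at least 2-fold. A change with stage remains, although E10.5 was sampled in R10 alone.

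Microglia core genes rose in BAM as well. Over the 17 genes called as rising the median rise was 9.48% of the microglial level. In each of the 4 BAM libraries at E18.5 it was at least 1.14 times the highest level of the 10 most restricted microglial genes. Both gene sets were picked by their levels in these same libraries, which raises that ratio. It therefore cannot exclude microglial RNA in the BAM libraries as the whole source of the median rise. Such RNA stays open for single genes too, since 3 of the 17 rises lay at or under the 5.75% that the restricted genes allow. Past 2 times that bound went 35.3% (6 genes), short of the 50% set beforehand. Of the rising genes, 100% stood above the highest E10.5 BAM library in the R10 library of E18.5 and in the mean of the R8 ones. They were chosen as higher in these same libraries, and R10 held 1 BAM library at E18.5, so this share cannot exclude the series. Over all 25 core genes the median log2 change within R10 was 0.954. A rise in BAM themselves may account for some of the median rise, a hypothesis found and tested on the same libraries.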

How the results depend on the processing

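No called gene list turned direction with RLE factors. An estimated correlation, the other alternative run for each list, changes the p-value and cannot turn the direction. Over these 2 settings list results lost their call 82 times. Of 291 gene results, 1 turned direction, Adam33 in the population-by-stage contrast. It ran from -1.72 (without microglia E10.5 replicate 3) to 5.14 (without BAM E10.5 replicate 3), and the cause was not tested. Across all settings gene results lost their call 43 times and kept it 6801 times. With a 2-fold threshold the calls were 578 at E10.5, 876 at E11.5, 1072 at E12.5, 1011 at E14.5, 1637 at E16.5, 1732 at E18.5 and 2159 for the mean, 4742 and 585 for microglia against E10.5 and E12.5, and 5407 and 935 for BAM. DESeq2 called 1623 genes at E10.5 (983 shared), and fits of the compared groups alone called 469 at E10.5, 855 at E11.5, 3603 at E16.5 and 3567 at E18.5, and the cause was not tested. With the R8 libraries of E18.5 left out, a setting chosen after seeing the data, calls were 1051 between populations at E18.5, 3743 and 819 for microglia against E10.5 and E12.5, 4212 and 989 for BAM, and 465 for the population-by-stage contrast. Leaving out 1 replicate gave 730 to 1012 calls at E10.5, 1102 to 1261 at E11.5, 1376 to 1767 at E12.5, 832 to 1401 at E14.5, 2224 to 2703 at E16.5, 2879 to 3077 at E18.5 and 5573 to 6355 for the mean. For E18.5 against E10.5 and E12.5 it gave 6804 to 7298 and 701 to 1507 in microglia, 7395 to 7860 and 1504 to 2160 in BAM, and 1236 to 1472 for the contrast. Sets called with an estimated in place of the preset correlation went from 11 to 6, 14 to 5, 18 to 6, 12 to 6, 11 to 5 and 13 to 6 in order of stage, 14 to 5 for the mean, 15 to 8 and 10 to 5 in microglia, 15 to 12 and 17 to 10 in BAM, and 10 to 6 for the contrast. With a 2-fold threshold 127 genes were higher and 160 lower at both E10.5 and E18.5. The first component held 53.04% with 2000 genes and 65.53% with RLE factors, and the second 11.95% and 12.68%. Blocks of adjacent library numbers gave 1257 calls at E10.5 and 1817 at E11.5, and at E14.5 kept 1298 of the 1584 main calls. Of 19 pairs of libraries with adjacent numbers 14 were most correlated with their own partner (median over pairs 0.252), a hint from the data and not from the labels. With the series as covariate 5387 genes were called for microglia and 5681 for BAM. Within E18.5 the series itself set 13 genes higher and 2 lower, with 2439 at unadjusted p below 0.05 by edgeR. Chance would put a share of 0.05 of the 22061 tested genes there, and 2439 is more than that. Since R10 held 1 library of each population at E18.5, the few calls do not show the series effect to be small. Depth limits calls for sparsely counted genes.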

Other observations

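Summed neural markers stood highest at E14.5, with 939.6 ± 57.1 CPM in microglia (n = 2) and 754.2 ± 116 in BAM (n = 3), against 112.9 ± 10.4 and 86.53 ± 18.2 at E10.5 and 272.3 ± 65 and 389.7 ± 125 at E18.5. Summed erythroid genes in microglia stood at 82.36 ± 52.2 at E10.5, 665.5 ± 74.4 at E12.5 and 240.9 ± 52.8 at E18.5. Lysosome genes in microglia went from 21010 ± 2220 to 71100 ± 6370 between E10.5 and E18.5, and in BAM from 23560 ± 263 to 39340 ± 2860. Mitosis genes went from 5195 ± 195 to 2393 ± 304 in microglia and from 5398 ± 296 to 1635 ± 251 in BAM. BAM core genes went from 9179 ± 2030 to 19170 ± 3160 in microglia and from 19580 ± 1150 to 61710 ± 4930 in BAM. Apoe weighed heavily in the microglial sum, at 1753 to 3289 CPM in the E10.5 libraries and 12320 to 19800 in the E18.5 ones. The BAM core list was not called as a set in microglia between these stages. Genes detected per library ranged from 19272 to 22696 in series R8 and from 17452 to 19975 in R10.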
